A study of Mus musculus with 22 samples.

How the data were processed

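RNA was sequenced from LSK cells, the lineage-negative, Sca-1-positive, Kit-positive gate of mouse bone marrow that holds stem cells and multipotent progenitors. Per the labels, cells were sorted from C57BL/6 mice 6 days after deletion was started with pI:pC, a double-stranded RNA that switches on interferon-driven Cre alleles, and were used without culture. The 12 RNA libraries fall into 4 genotypes with 3 libraries each, namely wild type (WT), Chd8 knockout (Chd8 KO), P53 knockout (P53 KO) and the double knockout (DKO). The series also lists 4 ATAC-seq and 6 CUT&RUN samples, which were not analysed here.

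The authors deposited 1 table of transcript-level TPM for each RNA library, and every table held the same 105129 transcripts of 33641 gene symbols. The submitters' processing notes name FastQC 0.11.7, Trim Galore 0.4.2, cutadapt 1.9.1, STAR 2.6.1e, Bowtie2 2.3.4.1, featureCounts 1.6.2, DESeq2 1.26.0, MACS2 2.1.2 and bedtools 2.27.0, with the GRCm38 (mm10) build, without saying which tool served which assay. The tool that made the TPM is not given in the sources used here. Each library's TPM summed to 1000000, so depth is unknown, no counting error can be given, and a rise in some genes lowers the share left for all others. How reads shared between near-identical copies were divided is not given in the sources used here, so pseudogenes and paralog families are uncertain. Run numbers carried by the tables put 10 libraries in 1 run and P53 KO replicates 1 and 2 in another.

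The TPM of the transcripts of a gene were summed. Genes with a mean of at least 1 TPM over the 12 libraries, 13162 in all, were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), with 1 mean per genotype and 8 residual degrees of freedom. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene comes from limma. The 6 contrasts were Chd8 KO against WT, P53 KO against WT, DKO against WT, DKO against Chd8 KO, DKO against P53 KO, and the interaction, which is the Chd8 effect without P53 minus the Chd8 effect with P53. Tables were read and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

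The contrasts, the lists and the rule for named genes were set before the data were examined. The 28 lists tested covered p53 targets, pro- and anti-apoptotic BCL-2 family members, DNA damage response and repair, S phase, G2/M, interferon-stimulated genes, inflammatory and NF-kB targets, hematopoietic stem cell, lymphoid priming, B cell, T and NK cell, myeloid progenitor, mature neutrophil and monocyte, erythroid, megakaryocyte and platelet, mast cell, basophil and eosinophil, macrophage and dendritic cell, endothelial and stromal genes, Wnt and beta-catenin targets, CHD remodelers, H3K4 and H3K27 methylation enzymes, ribosome biogenesis, cytoplasmic ribosomal proteins, nuclear oxidative phosphorylation genes, glycolysis, the unfolded protein and integrated stress response, and immediate early and dissociation stress genes. They were tested with limma's camera at a preset inter-gene correlation of 0.01, again with a correlation estimated for each list, and with fry, each adjusted over the lists. Named genes were Chd8, Trp53, Cdkn1a, Mdm2, Bax, Bbc3, Pmaip1, Atm, Kit and Ly6a. To these were added, in each pairwise contrast, the 8 largest rises and 8 largest falls (4 and 4 in DKO against WT). They were taken among called genes with at least 5 TPM in the higher group and no overlap between groups. The interaction gave 4 and 4 among called genes with at least 5 TPM in the highest group mean, and overlap was not checked there. Predicted models and antigen receptor variable segments were left out. Up to 4 members of each list with the smallest p were also named. Genes named outside this rule are said to be so.

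The fit was tested on simulated data with the mean and spread of each gene in these libraries and known changes in a seeded set of genes. Noise was drawn independently for each gene, without correlation between genes, a run difference or an outlying library. The shares below hold for that setting and need not hold for these libraries. For Chd8 KO against WT over 13162 genes, 40.3% of genes changed 1.5-fold, 70.2% of those changed 2-fold and 90.9% of those changed 4-fold were called, and 3.09% of calls fell on unchanged genes. For the interaction, the shares were 20.9%, 43.3% and 84.9%, with 3.48% of calls on unchanged genes.

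Alternatives changed 1 choice at a time. They were other pseudocounts (0.1 and 0.5), other low-value filters (none, or a mean of 5 TPM), median-of-ratios scaling, quantile normalization, TPM rescaled without mitochondrial and the top 20 genes, fits on only the groups compared, other variance models, a weight for each library, the replicate number as a block, the run as a covariate, only the run of 10 libraries, the most abundant transcript of each gene, a 2-fold minimum change, and leaving out each library in turn. The Y-linked level of each library as a covariate was added after the data had been seen. Gene positions were taken from RefSeq on GRCm38.p6 by symbol, and 12699 of the 13162 tested symbols matched. No library duplicated another, since correlations of log2(TPM + 1) between libraries ran from 0.905 to 0.978.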

Results

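Expression was measured by RNA sequencing in 12 libraries of LSK cells, the bone marrow gate that holds hematopoietic stem and multipotent progenitor cells, from WT, Chd8 KO, P53 KO and DKO mice, with 3 libraries each, 6 days after deletion was induced. The design asks what loss of CHD8, a chromatin remodeler, does to these cells and how far that depends on P53, the transcription factor that halts or kills damaged cells. Values are TPM as mean ± SD (n = 3), and changes are log2 fold changes of TPM + 1 ± SE from limma. Every gene named as among the largest changes of a pairwise comparison had no overlap between the libraries of its groups, so that all 3 libraries showed the direction. Overlap was not checked for the interaction. Depth is unknown, since each library summed to 1000000 TPM, and 12438 to 13236 genes reached 1 TPM. Nothing in the labels says that the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical. The summed level of 4 Y-linked genes was 126, 113 and 1.16 TPM in WT and 0.738, 50.1 and 1.35 TPM in P53 KO. These values argue against a single source for all libraries within either group, while Chd8 KO and DKO stay open.

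Chd8 (chromosome 14, 52198151 to 52258042, GRCm38) and Trp53 (chromosome 11, 69580348 to 69591873) followed the labels in every library. Chd8 stood at 67.4, 48.2 and 73.9 TPM in WT replicates 1 to 3 and at 53.1, 69.4 and 63.7 TPM in P53 KO. It stood at 28.5, 26.2 and 35.6 TPM in Chd8 KO and at 44.4, 34.8 and 44.1 TPM in DKO. Chd8 fell by 1.03 ± 0.18 in Chd8 KO against WT (adjusted p = 0.00357) and by 0.58 ± 0.18 in DKO against P53 KO (adjusted p = 0.0487), and the second call was lost when any of the DKO or P53 KO libraries was left out. Its most abundant transcript, ENSMUST00000200169.4, went from 26.9 ± 3.79 to 10.1 ± 2.35 TPM with P53 present and from 26.3 ± 2.73 to 11.8 ± 2.00 TPM without P53. Transcripts of the gene thus remained, and the position of the deleted part is not given in the sources used here. Trp53 stood at 268, 264 and 230 TPM in WT, at 268, 244 and 252 TPM in Chd8 KO, at 24.3, 22 and 17.5 TPM in P53 KO and at 17.1, 16.1 and 18.1 TPM in DKO. Its change in Chd8 KO against WT was 0.01 ± 0.11 (adjusted p = 0.981), a value whose sign turned under median-of-ratios scaling (-0.02) and quantile normalization (-0.06).

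Some library measures moved with the groups. P53 KO replicates 1 and 2 came from another run than the other 10 libraries, and mitochondrial transcripts made up 2.12% and 1.9% of their TPM, against 5.33% to 6.97% elsewhere. Ribosomal protein transcripts made up 23.6%, 21.2% and 20.6% of TPM in P53 KO, against 16.0% to 19.0% in the other groups. The summed level of 4 Y-linked genes was 126 and 113 TPM in WT replicates 1 and 2 and 94.2 to 116 TPM in Chd8 KO, but 1.16 TPM in WT replicate 3 and 1.80 to 2.03 TPM in DKO. In P53 KO it was 0.738, 50.1 and 1.35 TPM. Globin transcripts reached 812 and 1051 TPM in DKO replicates 2 and 3, against 39.7 to 175 TPM in the other 10 libraries.

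**Figure D1:**
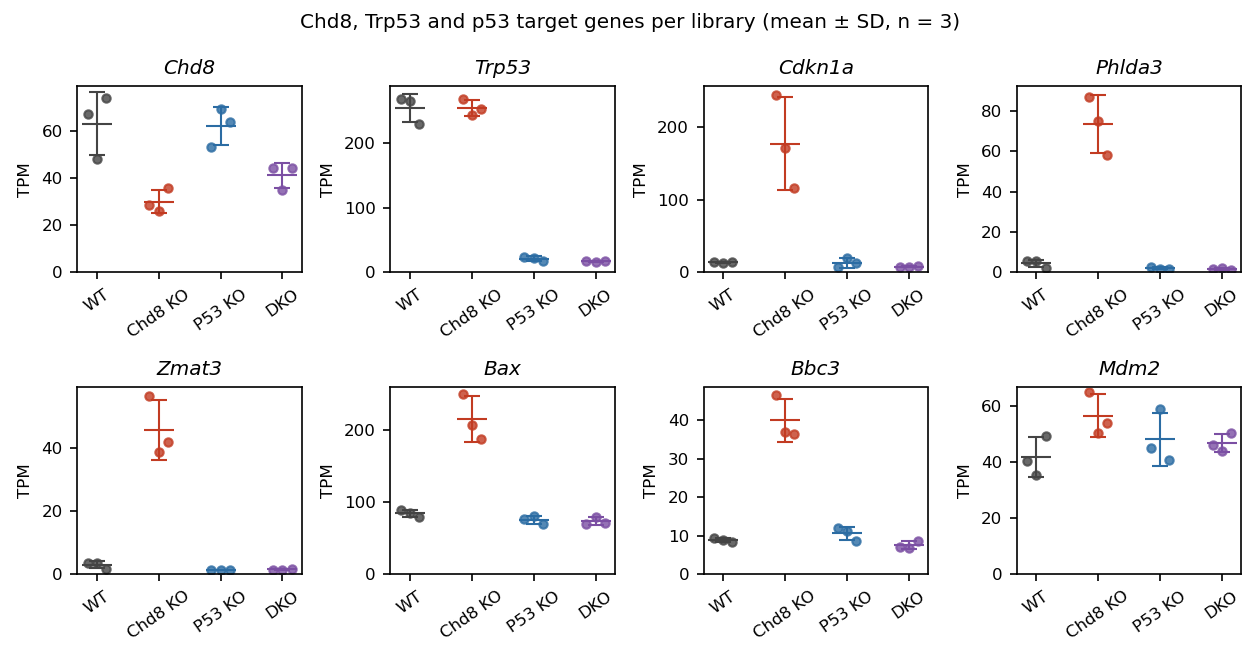
TPM of Chd8, Trp53 and 6 p53 pathway genes in each library, by genotype, with points for libraries and bars for the mean ± SD (n = 3). Cdkn1a stood at 177 ± 64.4 TPM in Chd8 KO and at 13.7 ± 0.801, 13.0 ± 6.32 and 7.93 ± 0.533 TPM in WT, P53 KO and DKO.

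In Chd8 KO against WT, direct targets of P53 rose together. Cdkn1a, the cell cycle inhibitor p21, rose from 13.7 ± 0.801 to 177 ± 64.4 TPM (3.54 ± 0.32, adjusted p = 7.32e-05). Phlda3, a repressor of AKT signalling, rose from 4.45 ± 1.79 to 73.4 ± 14.5 TPM (3.81 ± 0.26, adjusted p = 1.55e-05), and Zmat3, an RNA-binding protein, rose from 2.89 ± 1.06 to 45.6 ± 9.48 TPM (3.60 ± 0.21). The death receptor gene Eda2r rose by 3.35 ± 0.19, the heparan sulfatase gene Sulf2 by 3.68 ± 0.26 and the cyclin gene Ccng1 by 2.06 ± 0.14. Of 45 measured p53 targets, 32 rose and 0 fell over all genes tested, and 35 rose adjusted over the list alone, with a median change of 1.07. No member had a fall at an unadjusted p under 0.05 (count 0) by limma, and camera gave an adjusted p = 4.17e-21 for the list, with fry's adjusted p at 2.65e-06. Pro-apoptotic genes among them included Bbc3 (PUMA; 2.05 ± 0.15), Bax (1.33 ± 0.10) and Pmaip1 (NOXA; 1.51 ± 0.39, adjusted p = 0.024). Pmaip1 was not past the test without WT replicate 1 or 2 or Chd8 KO replicate 1 or 2. Mdm2, which encodes the ligase that degrades P53, was at 0.44 ± 0.16 (adjusted p = 0.0807), and Atm, a DNA damage kinase, was at 0.10 ± 0.15 (adjusted p = 0.705; -0.07 without WT replicate 2). Outside the list, Tnfsf4, the OX40 ligand, rose by 3.32 ± 0.18, Fam212b by 3.24 ± 0.18 and Zfp990, a zinc finger gene, by 3.40 ± 0.60.

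Genes of committed blood lineages fell in the same comparison. The largest falls included Igll1, a component of the surrogate light chain of pre-B cells (-5.26 ± 0.92, from 71.6 ± 39.3 to 0.701 ± 0.377 TPM), Cd79a, a signalling chain of the B cell receptor (-4.33 ± 0.82), and Dntt, the terminal transferase of lymphoid progenitors (-4.49 ± 0.68, from 316 ± 112 to 20.1 ± 20.1 TPM). They also included the eosinophil granule genes Ear2 (-5.00 ± 0.84), Epx (-4.84 ± 0.87) and Prg2 (-4.71 ± 0.72), the lipid kinase gene Sphk1 (-4.38 ± 0.60) and Rbpsuh-rs3 (-4.40 ± 0.94), whose level is uncertain because it is a copy of Rbpj. By list, 15 of 22 lymphoid priming genes fell (17 adjusted over the list alone), among them Tcf7 (-2.22 ± 0.20) and Il7r (-3.27 ± 0.40). So did 11 of 16 B cell genes (13 adjusted over the list alone) and 7 of 13 T and NK cell genes (7 adjusted over the list alone), such as Trbc1 (-2.93 ± 0.18). Of 26 erythroid genes, 14 fell (17 adjusted over the list alone), among them Ermap (-3.83 ± 0.58) and the blood group antigen gene Rhd (-3.29 ± 0.58). That erythroid count was 8 without WT replicate 1, WT replicate 2, Chd8 KO replicate 2 or Chd8 KO replicate 3 and 9 without Chd8 KO replicate 1. Of 19 mast cell, basophil and eosinophil genes, 8 fell and 2 rose (11 and 2 adjusted over the list alone). Of 21 macrophage and dendritic cell genes, 8 fell (10 fell and 4 rose adjusted over the list alone), with 4 without WT replicate 1 and 5 without WT replicate 3, Chd8 KO replicate 1 or Chd8 KO replicate 3. Of 19 megakaryocyte and platelet genes, 4 fell (7 adjusted over the list alone), such as Itga2b (-0.97 ± 0.14). In all 6 of these lists other than the macrophage list, camera's adjusted p lay between 1.82e-11 (lymphoid priming) and 0.00306 (megakaryocyte), and it was 0.0292 for the macrophage list. With a correlation estimated for each list, T and NK cell genes kept the call (adjusted p = 0.0401 with an estimated correlation) and the others lost it, at 0.0841 for lymphoid priming, 0.374 for B cell, 0.426 for erythroid, 0.52 for megakaryocyte and 0.492 for the mast cell and macrophage lists. Fry's adjusted p was 1.6e-06 for T and NK cell, 0.00019 for lymphoid priming, 0.0066 for B cell and 0.0257 for erythroid genes. It was 0.038 for the mast cell and macrophage lists and 0.0899 for megakaryocyte genes, which did not pass.

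Mature neutrophil and monocyte genes did not move with those lineages. None of the 18 measured passed the test by limma (1 was higher and 0 lower at an unadjusted p under 0.05, and 0 adjusted over the list alone), and the list's median was 0.31. S100a8, a calcium-binding protein gene of neutrophils, stood at 16.3, 4.31 and 253 TPM in WT replicates 1 to 3, so the WT libraries differ among themselves here. Without WT replicate 3, 8 of the 18 genes were higher in Chd8 KO. Among 34 hematopoietic stem cell genes, 7 rose and 1 fell (9 and 2 adjusted over the list alone; 3 or 4 rose without WT replicate 2 or 3 or any Chd8 KO library). The list did not pass camera's test (adjusted p = 0.204, and adjusted p = 0.849 with an estimated correlation) or fry's (adjusted p = 0.406). Slamf1, the stem cell surface marker CD150, went from 6.54 ± 1.07 to 18.4 ± 2.15 TPM (1.36 ± 0.17, adjusted p = 0.000537), Tek, the angiopoietin receptor, rose by 1.02 ± 0.17, and Runx1 fell by 0.49 ± 0.10. Of the genes of the sort gate, Kit was at -0.18 ± 0.16 (adjusted p = 0.47) and Ly6a, which encodes Sca-1, at 1.01 ± 0.30 (adjusted p = 0.044), a call lost in 13 of the alternatives, both scalings among them.

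Of 53 cytoplasmic ribosomal protein genes, 17 fell and 1 rose in Chd8 KO (18 and 3 adjusted over the list alone; camera adjusted p = 1.32e-05), with 11 falls without WT replicate 1, WT replicate 2 or Chd8 KO replicate 3 and 9 without Chd8 KO replicate 1. Ribosome biogenesis genes rose in 8 of 30 cases (9 adjusted over the list alone; camera adjusted p = 0.000122). Oxidative phosphorylation genes rose in 10 and fell in 1 of 38 (14 and 1 adjusted over the list alone; 2.46e-06). Glycolysis genes rose in 6 and fell in 1 of 19 (9 and 2 adjusted over the list alone; 0.0155). Ribosome biogenesis rises numbered 3 without WT replicate 1, 4 without WT replicate 3 and 2, 3 and 4 without Chd8 KO replicates 1 to 3. Oxidative phosphorylation rises numbered 5 without WT replicate 1 or 3, 4 without Chd8 KO replicate 2 and 6 without Chd8 KO replicate 3, and glycolysis rises 2 without Chd8 KO replicate 1. These 4 lists lost camera's call, with an adjusted p of 0.426 for glycolysis and 0.492 for the others with an estimated correlation, so that of the 12 lists past camera's test, p53 targets (0.0401) and T and NK cell genes kept it. Fry's adjusted p was 0.0136 for glycolysis, 0.0158 for oxidative phosphorylation, 0.0279 for cytoplasmic ribosomal proteins and 0.031 for ribosome biogenesis.

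The other lists that did not pass camera's test gave the following counts of rises and falls. They were 3 and 1 of 9 pro-apoptotic BCL-2 family genes, 1 and 1 of 5 anti-apoptotic ones, 4 and 1 of 35 DNA damage response genes, and 2 and 0 of 28 S phase genes. Others were 2 and 1 of 28 G2/M genes, 1 and 0 of 40 interferon-stimulated genes, 1 and 3 of 14 inflammatory genes and 1 and 3 of 23 myeloid progenitor genes. They were 0 and 2 of 14 endothelial and stromal genes, 2 and 6 of 15 Wnt targets, 0 and 2 of 9 CHD remodelers, 1 and 2 of 26 H3K4 and H3K27 methylation enzymes, 1 and 3 of 19 unfolded protein and integrated stress response genes, and 1 and 0 of 21 immediate early genes. Fry passed the pro-apoptotic BCL-2 list (adjusted p = 0.00013), which shares Bax, Bbc3 and Pmaip1 with the p53 targets, and Wnt targets (0.0308). For the other lists of this group fry's adjusted p was 0.289 or more. For endothelial and stromal genes the median (0.44) and mean (0.17) were positive while camera's direction was down, and camera's direction was also down for interferon-stimulated genes, with a median of 0.00. Without WT replicate 3, 15 interferon-stimulated genes rose, and 8 with the Y-linked level as a covariate. Immediate early genes fell in 6 cases without P53 KO replicate 3 and in 9 in the run of 10 libraries alone. With 1 library left out, falls numbered 3 to 7 for Wnt targets and 0 to 5 for unfolded protein and integrated stress response genes, and rises 2 to 4 for DNA damage response and 1 to 5 for S phase genes, while the other counts of these lists moved by no more than 1 gene. The falls among CHD remodelers were Chd8 itself and Chd6 (-0.67 ± 0.21, adjusted p = 0.0485).

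In all, 2189 of 13162 genes changed in Chd8 KO against WT by limma, 1270 higher and 919 lower, and 564 of them by at least 2-fold. Groups did not overlap for 37.1% of genes, where chance gives 10%. With median-of-ratios scaling 1039 genes were higher and 1144 lower, so the split between directions rests on the scaling. The count was 1278 without WT replicate 1, and 1154, 1301 and 1417 without Chd8 KO replicates 1, 2 and 3.

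**Figure D2:**
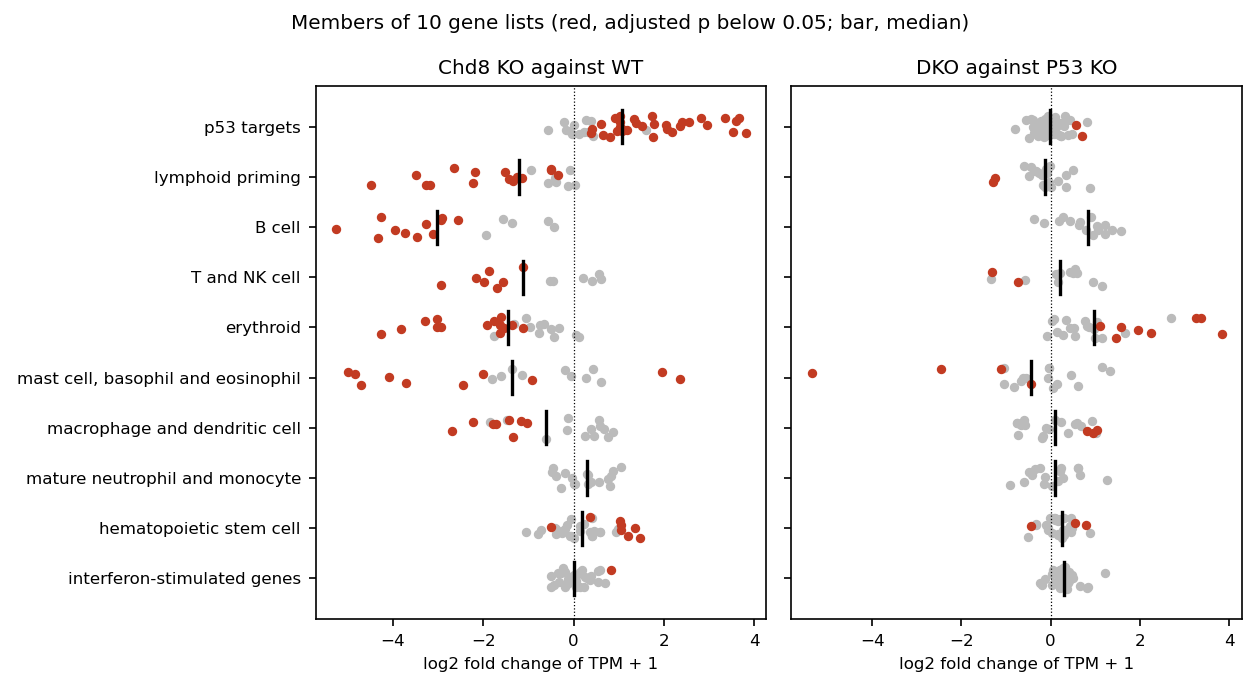
log2 fold change of each measured member of 10 gene lists in Chd8 KO against WT and in DKO against P53 KO, with red points for members past the test and a bar at the list's median. The medians of the p53 targets were 1.07 and -0.02, those of the B cell genes -3.03 and 0.85 and those of the erythroid genes -1.45 and 0.97, and the values without P53 turned to 0.08, -0.70 and -0.14 in the run of 10 libraries alone.

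Loss of P53 alone left few changes past the test. Against WT, 24 genes changed in P53 KO by limma, 10 higher and 14 lower, with 1931 at an unadjusted p under 0.05. Trp53 fell by 3.52 ± 0.11 (adjusted p = 3.51e-08). Sat2, a polyamine acetyltransferase gene on the same chromosome that starts at 69621996, rose from 0.305 ± 0.136 TPM (4.01 ± 0.17), to 20.7, 22.4 and 17.1 TPM. No p53 target changed (0 of 45; 2 higher and 6 lower at an unadjusted p under 0.05, and 2 lower adjusted over the list alone). Cdkn1a was at -0.17 ± 0.32 (adjusted p = 0.855), Bax at -0.16 ± 0.10 (0.505), Bbc3 at 0.22 ± 0.15 (0.506), Pmaip1 at -0.31 ± 0.39 (0.756) and Mdm2 at 0.20 ± 0.16 (0.581).

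Many of the other changes lay near Chd8 on chromosome 14, although Chd8 itself was at -0.01 ± 0.18. Rises there included Ear1, an eosinophil-associated ribonuclease gene (4.64 ± 0.60), Rnase12 (2.84 ± 0.36), Ppp1r3e, a glycogen phosphatase subunit gene (2.40 ± 0.21), the meiotic cohesin gene Rec8 (1.96 ± 0.21), Rpgrip1 (1.67 ± 0.23) and the proteasome subunit gene Psmb5 (0.91 ± 0.09). Falls there included Mcpt2, a mast cell protease gene (-4.97 ± 0.55), Ccnb1ip1 (-3.55 ± 0.19) and the phosphatase-like gene Mtmr9 (-1.98 ± 0.25). Of the 24 genes, 11 lay within 15 Mb of Chd8, a window chosen after the data were seen, and 3, Trp53 included, within 15 Mb of Trp53. On chromosome 4, between 106315980 and 106679002, Usp24 (-1.32 ± 0.18), Ttc4 (-1.05 ± 0.14) and Pars2 (-0.96 ± 0.12) fell, and Nat8f1 on chromosome 6 rose (1.05 ± 0.16). Pars2, Ttc4 and Usp24 were also lower in Chd8 KO (6.93, 20.3 and 15.3 TPM) and in DKO (6.77, 19.6 and 17.8 TPM) than in WT (12.5, 43.7 and 36.3 TPM).

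Ribosomal protein genes stood higher in P53 KO, with a median of 0.24 and 0 of 53 past the test over all genes but 33 higher adjusted over the list alone (39 at an unadjusted p under 0.05; camera adjusted p = 5.70e-25, and adjusted p = 0.252 with an estimated correlation). The same shift is in the libraries' ribosomal protein shares. Camera also passed S phase (median -0.18), ribosome biogenesis (-0.16), DNA damage response (-0.16), B cell (-1.50), T and NK cell (-0.38) and endothelial and stromal genes (0.39), each with an adjusted p of 0.197 or more with an estimated correlation. Il2rb, a cytokine receptor chain of T and NK cells, was the member of those 6 lists past the test. Lists passed camera's preset test in other splits of these libraries too, up to 13 of 28 here and up to 17 for Chd8 KO against WT. The count of 24 rose to 1253 without P53 KO replicate 3, which left the 2 libraries of the other run to stand for the group, and the B cell median turned to 0.14 in the run of 10 libraries alone. With quantile normalization 14 genes were higher and 13 lower.

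In DKO against WT, Trp53 fell by 3.82 ± 0.11 and Sat2 rose by 3.51 ± 0.17, while Chd8 was at -0.59 ± 0.18 (adjusted p = 0.0780), not past the test. C2cd4a rose from 0.0562 ± 0.0504 to 10.7 ± 5.42 TPM (3.33 ± 0.36), the cytidine deaminase gene Cda by 3.15 ± 0.49 and the kelch-repeat gene Klhdc8b by 2.47 ± 0.23. The histone gene Hist1h2ao fell by 3.21 ± 0.41, although its family of near-identical copies makes its level uncertain. So did the zinc finger gene Zfp580 (-2.31 ± 0.22) and the histidine phosphatase gene Phpt1 (-2.27 ± 0.17). No p53 target changed by limma (0 of 45; 2 higher and 5 lower at an unadjusted p under 0.05; 0 adjusted over the list alone), with Cdkn1a at -0.72 ± 0.32 (adjusted p = 0.215), Bax at -0.20 ± 0.10 (0.291) and Bbc3 at -0.22 ± 0.15 (0.422). The list passed camera's test downward (median -0.09, camera adjusted p = 0.0435, and adjusted p = 0.719 with an estimated correlation).

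Few lymphoid genes passed the test in DKO against WT. Of 16 B cell genes, 0 changed by limma (0 higher and 1 lower at an unadjusted p under 0.05; 0 adjusted over the list alone). Of 22 lymphoid priming genes 2 fell (4 adjusted over the list alone), among them Tcf7 (-1.21 ± 0.20). Of 13 T and NK cell genes 4 fell (5 adjusted over the list alone), such as Trbc1 (-1.49 ± 0.18), with 2 without WT replicate 2 or DKO replicate 2. Camera nonetheless passed each of these lymphoid lists downward. The medians were -0.66 for B cell (camera adjusted p = 0.0042), -0.14 for lymphoid priming (0.0071) and -0.77 for T and NK cell genes (0.00043). With an estimated correlation, camera's adjusted p was 0.719 for B cell and lymphoid priming genes and 0.0761 for T and NK cell genes. Mature neutrophil and monocyte genes lay lower here, with a median of -1.07 (camera adjusted p = 0.00846, and adjusted p = 0.719 with an estimated correlation). None of the 18 passed by limma (0; 1 higher and 6 lower at an unadjusted p under 0.05; 0 adjusted over the list alone), and 8 were lower with the Y-linked level as a covariate. Of 40 interferon-stimulated genes 0 rose and 1 fell (0 and 0 adjusted over the list alone), but 20 rose without WT replicate 3 and 7 fell with the Y-linked level as a covariate. Of 26 erythroid genes 3 rose (6 adjusted over the list alone), among them Alas2, the heme synthesis enzyme of red cells (1.42 ± 0.34), with counts from 0 without DKO replicate 3 to 8 without P53 KO replicate 3, and the globin level was high in DKO replicates 2 and 3. Cytoplasmic ribosomal protein genes fell in 12 of 53 cases (18 adjusted over the list alone), with 7, 5 and 6 without WT replicate 1 and DKO replicates 1 and 2 and 6 with quantile normalization. In the same list 1 gene rose (3 adjusted over the list alone), and with the Y-linked level as a covariate 4 fell and 2 rose. Of the 14 lists past camera's test none held with an estimated correlation (0 lists), the smallest adjusted p being 0.0761, for T and NK cell genes.

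In all, 688 genes changed in DKO against WT, 455 higher and 233 lower, and groups did not overlap for 31.2% of genes, where chance gives 10%. With median-of-ratios scaling 252 were higher and 380 lower, and the level of Y-linked transcripts as a covariate left 298. The count was 366 and 426 without WT replicates 1 and 2, 332, 318 and 283 without DKO replicates 1 to 3 and 1049 without P53 KO replicate 3.

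DKO against Chd8 KO asks what P53 loss changes where Chd8 is already lost. The p53 targets fell, with Phlda3 at -4.81 ± 0.26, Sulf2 at -4.39 ± 0.26, Cdkn1a at -4.26 ± 0.32, Zmat3 at -4.24 ± 0.21, Bbc3 at -2.27 ± 0.15 and Bax at -1.54 ± 0.10, and Tnfsf4 fell by 3.95 ± 0.18. Of 45 targets, 29 fell and 1 rose (32 and 3 adjusted over the list alone; camera adjusted p = 8.62e-30, and adjusted p = 0.028 with an estimated correlation). Genes of several lineages rose, led by Igll1 (4.84 ± 0.92), the peptide transporter gene Slc15a2 (4.81 ± 0.88), Epx (4.58 ± 0.87), Ear2 (4.44 ± 0.84), Prg2 (4.38 ± 0.72), Ear6 (4.16 ± 0.82) and the beta-globin gene Hbb-bt (3.99 ± 1.01). Of 26 erythroid genes 23 rose (24 adjusted over the list alone), of 22 lymphoid priming genes 10 (14), and of 16 B cell genes 8 (12). Rises numbered 5 of 13 T and NK cell genes with 1 fall (8 and 2 adjusted over the list alone), 6 of 21 macrophage and dendritic cell genes with 1 fall (6 and 1) and 5 of 19 megakaryocyte genes (8). With 1 library left out, macrophage and dendritic cell rises numbered 3 to 8 and megakaryocyte rises 2 to 6, the fewest in both without DKO replicate 3. Mature neutrophil and monocyte genes went the other way, with a median of -1.28, 0 falls and 1 rise over all genes tested by limma (2 higher and 8 lower at an unadjusted p under 0.05) and 8 falls and 1 rise adjusted over the list alone. Camera's adjusted p for them was 0.0105 (adjusted p = 0.792 with an estimated correlation), and 10 fell without WT replicate 3.

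S phase genes fell in 7 of 28 cases (13 adjusted over the list alone), among them Mcm2 (-0.40 ± 0.08), with 0 to 9 over fits that each left out 1 library. Glycolysis genes fell in 5 of 19 (6 adjusted over the list alone, with 1 rise), among them Pkm (-0.83 ± 0.14), with 3 to 6. With the Y-linked level as a covariate, 0 S phase and 0 glycolysis genes fell, and 1 glycolysis gene rose. Camera passed 14 lists, of which p53 targets held with an estimated correlation. The adjusted p there was 0.0625 for pro-apoptotic BCL-2 genes, 0.184 for lymphoid priming and for T and NK cell genes, 0.273 for erythroid, 0.454 for B cell, 0.447 for S phase, 0.336 for glycolysis and 0.501 or more for the rest. The falls also included the Y-linked genes Eif2s3y (-5.57 ± 1.52) and Ddx3y (-4.57 ± 1.24) and the pseudogene Rpl15-ps2 (-7.49 ± 1.86), which cannot be told from its parent gene with certainty. Kit was at 0.37 ± 0.16 (adjusted p = 0.164) and Ly6a fell by 1.23 ± 0.30 (adjusted p = 0.0289, lost without Chd8 KO replicate 1 or 2 or any DKO library).

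The summed Y-linked level was 94.2 to 116 TPM in the 3 Chd8 KO libraries and 1.80 to 2.03 TPM in the DKO libraries. Y-linked genes are carried by male mice only. By these transcripts the groups differ in sex, so this comparison alone cannot separate P53 loss from sex. With the Y-linked level as a covariate, which varies within WT and P53 KO, 183 genes in place of 1386 were called. In all 23 p53 targets fell there, 22 of the 29 among them, and over the 29 the mean change went from -2.13 to -2.08 and the median SE from 0.19 to 0.29, so their fall does not rest on the Y-linked difference alone. By list, 2 erythroid, 2 lymphoid priming and 0 B cell genes rose with the covariate. Of the 62 lineage genes that fell in Chd8 KO against WT, 47 rose in DKO against Chd8 KO and 4 with the covariate. Over the 62 the mean change went from 2.20 to 1.97 and the median SE from 0.41 to 0.62. The mean change thus moved little while the SE grew, which lowers the number of calls. With few calls left, the Y-linked difference stays open for these genes. The 1386 were 832 higher and 554 lower, or 742 and 831 with median-of-ratios scaling and 645 and 753 with quantile normalization, and groups did not overlap for 41.9% of genes, where chance gives 10%. The count was 524, 734 and 917 without Chd8 KO replicates 1 to 3 and 630, 831 and 539 without DKO replicates 1 to 3. Erythroid rises numbered 14 without Chd8 KO replicate 1 or 3, 15 without DKO replicate 2 and 13 without DKO replicate 3, and B cell rises 4 without any 1 of the Chd8 KO libraries or DKO replicate 1 or 3.

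DKO against P53 KO asks what Chd8 loss changes where P53 is missing. The p53 targets did not rise as a group, with 2 of 45 higher (1 adjusted over the list alone), Aen (0.57 ± 0.09) and Rrm2b (0.70 ± 0.18), a list median of -0.02 and Cdkn1a at -0.55 ± 0.32 (adjusted p = 0.263). That count was 1 without P53 KO replicate 1 or any DKO library, 4 without P53 KO replicate 3 and 0 in the run of 10 libraries alone. Cytoplasmic ribosomal protein genes fell in 30 of 53 cases with 1 rise (37 and 2 adjusted over the list alone), among them Rps4x (-1.04 ± 0.07) and Rpl37 (-1.17 ± 0.09). Of 30 ribosome biogenesis genes 15 rose (21 adjusted over the list alone), among them Npm1 (0.49 ± 0.08), with 7 without DKO replicate 2, 8 without P53 KO replicate 1 and 10 without DKO replicate 3, and 5 with median-of-ratios scaling. The ribosomal protein share of TPM was 16.6% to 17.1% in DKO against 20.6% to 23.6% in P53 KO. Camera's adjusted p was 9.90e-29 and 1.08e-05 for these lists (adjusted p = 0.181 and 0.878 with an estimated correlation).

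Globin genes were among the largest rises. Hbb-bs rose by 3.83 ± 0.65, to 58.2, 324 and 513 TPM, with Hba-a1 (3.38 ± 0.60) and Hba-a2 (3.27 ± 0.60). Of 26 erythroid genes 8 rose (9 adjusted over the list alone; adjusted p = 0.978 with an estimated correlation). That count was 4 without P53 KO replicate 1 or DKO replicate 2, 5 without DKO replicate 3 and 19 without P53 KO replicate 3. C2cd4a rose by 3.35 ± 0.36, Ifi44l, an interferon-induced gene, by 5.37 ± 1.13, and the pseudogene-like Rps12l1 by 7.49 ± 2.14. Ifi44l stood at 37.9, 19.5, 0.013 and 40.9 TPM in WT, Chd8 KO, P53 KO and DKO. Rps12l1 stood at 218, 30.0, 0 and 285 TPM in that order. Both rises thus rest on levels near 0 in P53 KO, while DKO stood near or above WT. None of the 40 interferon-stimulated genes passed by limma (0 at an unadjusted p under 0.05, and 0 adjusted over the list alone), but 7 rose without WT replicate 3. Zfp580 (-2.74 ± 0.22), Phpt1 (-2.53 ± 0.17), the basophil protease gene Prss34 (-2.45 ± 0.45), Dmwd (-2.13 ± 0.21) and the fatty acid binding gene Fabp4 (-2.11 ± 0.62) fell. Mcpt2 (3.64 ± 0.55), Ccnb1ip1 (3.39 ± 0.19), Ear1 (-5.35 ± 0.60) and Rnase12 (-2.82 ± 0.36), all near Chd8 on chromosome 14, changed opposite to their change in P53 KO against WT, and 55 of 198 tested genes within 15 Mb of Chd8 were called against 14.8% elsewhere. The other lists past camera's test were pro-apoptotic BCL-2 genes, lymphoid priming, mast cell, basophil and eosinophil, endothelial and stromal, and immediate early genes, with an adjusted p of 0.181 or more each with an estimated correlation.

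In all, 1957 genes changed in DKO against P53 KO, 1471 higher and 486 lower. The median over all genes was 0.11, and median-of-ratios scaling, which moved it to 9.0e-04, gave 557 higher and 756 lower, and quantile normalization 662 and 723. Groups did not overlap for 35.3% of genes, where chance gives 10%. In the run of 10 libraries alone, where P53 KO has 1 library whose spread is assumed to be that of the other groups, 298 genes were called, 222 of them among the 1957. There were 0 erythroid, 0 ribosome biogenesis and 13 falling ribosomal protein genes among them, and the erythroid median turned to -0.14. The count was 676, 1244 and 3089 without P53 KO replicates 1 to 3 and 794, 675 and 725 without DKO replicates 1 to 3.

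The Chd8 effect was then compared between the backgrounds. The interaction passed limma's test for 237 genes, 127 with a higher and 110 with a lower change without P53. Of 198 tested genes within 15 Mb of Chd8, 14 were called (7.07% against 1.74% elsewhere; Fisher's exact two-sided p = 1.55e-05, over genes that are not independent and in a window chosen after the data were seen). Its largest negative values were at p53 targets, namely Cdkn1a (-4.09 ± 0.45), Phlda3 (-3.99 ± 0.37), Sulf2 (-3.83 ± 0.36) and Zmat3 (-3.53 ± 0.30), with Bbc3 at -2.49 ± 0.21 and Bax at -1.38 ± 0.15. Of 45 p53 targets 22 had a lower change without P53 (28 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.59e-32), and 18 in the run of 10 libraries alone. Its largest positive values were at Igll1 (6.83 ± 1.31), Ear2 (6.33 ± 1.19), Cd79a (5.38 ± 1.16) and the B cell adaptor gene Blnk (4.98 ± 0.84), and none of these 4 passed in the run of 10 libraries alone. Ear2 starts at 44102654 on chromosome 14, inside that window. Of 13 T and NK cell genes 5 had a higher change (8 higher and 1 lower adjusted over the list alone), of 26 erythroid genes 13 (24), of 16 B cell genes 6 (13) and of 22 lymphoid priming genes 3 (13). The run of 10 libraries alone gave 2, 0, 0 and 1 of them. Chd8 itself was at 0.45 ± 0.25 (adjusted p = 0.333).

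Camera passed 12 lists for the interaction, and p53 targets (adjusted p = 0.0168 with an estimated correlation), pro-apoptotic BCL-2 genes (0.0168) and T and NK cell genes (0.026) held. Of the 9 measured pro-apoptotic genes 3, namely Bax, Bbc3 and Pmaip1, are also on the p53 target list. The 2 called by limma for the interaction were Bax and Bbc3, so these lists are not separate evidence. For the rest the adjusted p with an estimated correlation was 0.261 for erythroid and lymphoid priming, 0.297 for B cell and cytoplasmic ribosomal proteins, 0.381 for glycolysis and 0.71 or more for the other 4. The median interaction over all genes was 0.10, and with quantile normalization, which moved it to -0.03, 86 genes were higher and 170 lower. The count of 237 was 122 without WT replicate 1, 142 and 144 without Chd8 KO replicates 1 and 2, 138, 125 and 1562 without P53 KO replicates 1 to 3 and 136, 133 and 128 without DKO replicates 1 to 3. Erythroid calls ranged from 0 without WT replicate 1 to 22 without P53 KO replicate 3, B cell calls from 3 to 12 and lymphoid priming calls from 1 to 9, the highest again without P53 KO replicate 3.

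Across genes, the changes with and without P53, which share no library, had a Pearson correlation of 0.126 and a Spearman correlation of 0.268 over 13162 genes, which are not independent replicates. Of the 2189 genes changed in Chd8 KO against WT, 1716 (78.4%) had the same sign in DKO against P53 KO. There were 685 genes called in both, 659 with the same sign, where 176 would be met by independent lists. Both lists use 1 spread per gene from all 12 libraries, so they are not fully independent and 176 is not an exact chance level. The correlation was 0.234 in the run of 10 libraries alone and 0.0473 without P53 KO replicate 3. Phpt1 and Zfp580 were among the shared changes, at means of 68.7 and 7.14 TPM in WT, 10 and 0.288 TPM in Chd8 KO, 83.0 and 10.1 TPM in P53 KO and 13.4 and 0.677 TPM in DKO.

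**Figure D3:**
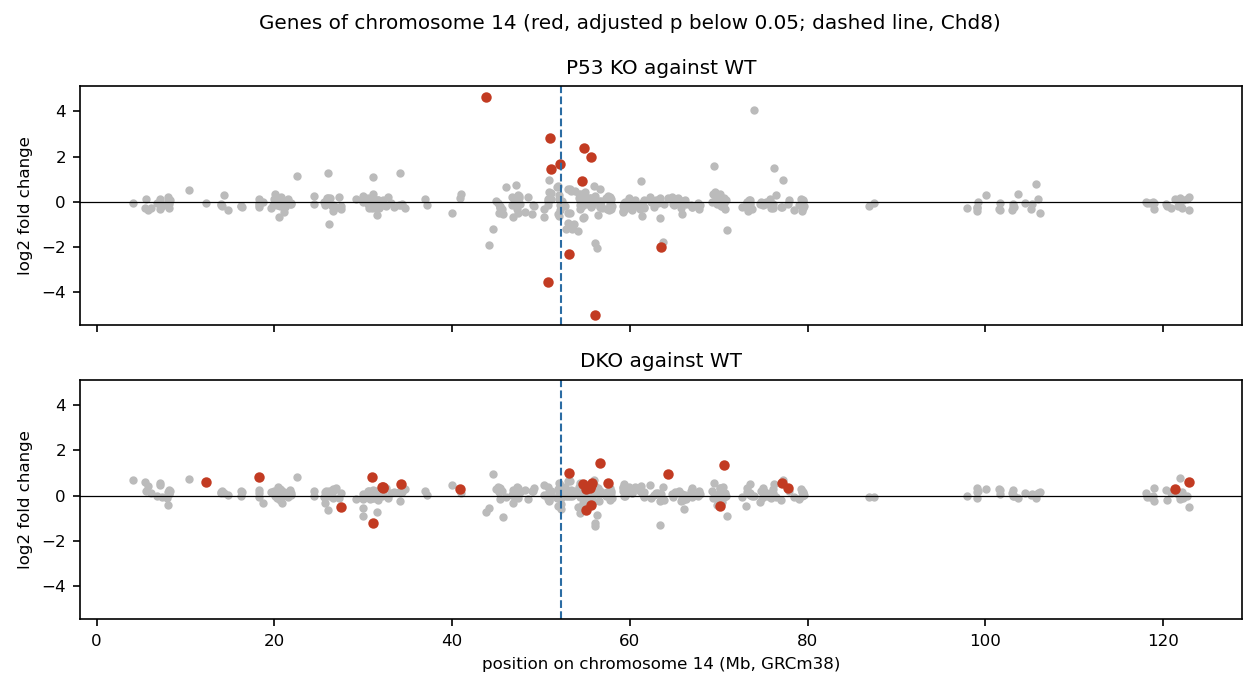
log2 fold change of each tested gene of chromosome 14 against its position in Mb (GRCm38), in P53 KO against WT and in DKO against WT, with red points for genes past the test and a dashed line at Chd8. In P53 KO against WT 11 of the 24 genes past the test lie within 15 Mb of Chd8. Of these 11, 1 passes in DKO against WT, where its change has the opposite sign (-2.30 in P53 KO and 0.98 in DKO).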

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

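All tests weighed here were chosen after the result was seen, except the fit without WT replicate 3, the ratio of changes between runs and the splits of the libraries. The difference of the Chd8 effect between backgrounds passed limma's test for 237 genes, and these are flagged because the groups differ. Genes of the p53 pathway changed less without P53, at -4.09 for Cdkn1a, -3.99 for Phlda3, -3.83 for Sulf2, -3.53 for Zmat3, -3.29 for Eda2r, -2.49 for Bbc3 and -1.38 for Bax. Outside the p53 target list, Fam212b was at -3.23 and Tnfsf4 at -3.22. Lineage genes differed the other way, at 6.83 for Igll1, 6.33 for Ear2, 5.38 for Cd79a and 4.98 for Blnk, and Ear2 lies within 15 Mb of Chd8, where 7.07% of genes were called for the difference against 1.74% elsewhere. Of the 12 lists past camera's preset test, p53 targets, pro-apoptotic BCL-2 genes and T and NK cell genes kept the call with an estimated correlation and 9 lost it (adjusted p from 0.261 to 0.932). The p53 target and pro-apoptotic lists share Bax, Bbc3 and Pmaip1, so they are not separate evidence. Median differences of the 12 lists were -0.89 for p53 targets, -0.35 for pro-apoptotic BCL-2 genes, -1.07 for endothelial and stromal genes, -0.22 for cytoplasmic ribosomal proteins and -0.17 for glycolysis. The medians were -0.0941 for oxidative phosphorylation, -0.0464 for S phase and -0.0468 for G2/M, and 3.66 for B cell, 2.99 for erythroid, 1.59 for T and NK cell and 0.605 for lymphoid priming genes. A Trp53 transcript, ENSMUST00000171247.7, was flagged as a signal not described by the gene totals. It stood at 11.9 TPM or more (highest 18.8 TPM) in all 6 libraries without P53, at 15.6 ± 3.46 TPM in P53 KO and 13.8 ± 1.79 TPM in DKO, and at 0 in all 6 libraries with P53.

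With Chd8 and Trp53 left out, 13 of the 23 calls in P53 KO against WT lay within 15 Mb of them (2.37% of the genes there against 0.0823% elsewhere; Fisher's exact two-sided p = 1.21e-12), but the window was set after the clustering was seen, so this p describes it and tests no cause. Chromosome segments linked to the targeted alleles, such as sequence carried over from the strain in which an allele was made, stay open. In DKO against Chd8 KO, whose libraries did not prompt the test, 44 of 351 genes near Trp53 were called (12.5% against 10.6% elsewhere, Fisher's exact two-sided p = 0.254). In DKO against WT, which shares the WT libraries that prompted the test, 31 of 351 were called (8.83% against 5.22% elsewhere, Fisher's exact two-sided p = 0.0052). Near Chd8 the 11 calls all changed back in DKO against P53 KO. That comparison holds the P53 KO libraries that picked the genes, so any cause confined to P53 KO, the run included, could give this. A segment would have to differ between mouse lines, and no genotype of these regions was used here to test that. The run of 2 of the 3 P53 KO libraries does not account for the calls near Trp53 other than Trp53 itself, since both passed in DKO against Chd8 KO (2 of 2; 3.80 ± 0.17 for Sat2 and 2.43 ± 0.17 for Shbg, which lies outside the rule for naming genes), whose libraries all come from 1 run and did not pick them. Of the 11 near Chd8, 6 passed in the run of 10 libraries alone, and 5 kept their sign with a larger error, at 1.47 ± 0.20 and 1.16 ± 0.25 for Ang, which lies outside the rule too, 1.67 ± 0.23 and 1.76 ± 0.33 for Rpgrip1, 1.96 ± 0.21 and 1.81 ± 0.32 for Rec8, -4.97 ± 0.55 and -5.34 ± 0.79 for Mcpt2 and -1.98 ± 0.25 and -1.85 ± 0.39 for Mtmr9, but that fit holds 1 P53 KO library, which also helped to pick the genes, so the run stays open for all 11.

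A purer sort would lower all mature lineages in Chd8 KO, but neutrophil and monocyte genes had a mean of 0.24 against -1.50 for the other lineage genes (two-sided permutation p over genes, which are not independent, = 1.0e-05), though loss of 1 population from the gate could still do this. Of the 62 lineage genes that fell, 52 still passed without WT replicate 3, the WT library with a low Y-linked level (1.16 TPM), and 43 without WT replicate 1. A less complete deletion in DKO would leave a share of the change near that of Chd8 itself, 0.634, if lineage genes change in proportion to Chd8. The median share seen again in DKO against P53 KO was -0.124 (quartiles -0.379 and 0.192). That share mixes the runs of the P53 KO libraries and uses genes picked for their fall in Chd8 KO. It therefore cannot exclude a less complete deletion. In DKO against P53 KO, whose libraries did not pick the genes, 5 of the 62 fell, which is consistent with dependence on P53, but their mean change was 0.26 there and -0.58 in the run of 10 libraries alone, so a partial fall without P53 stays possible. An earlier form of this test, the interaction adjusted over these genes alone, gave 57 of 62 and was replaced because the genes had been picked on a part of it.

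The run of 2 of the 3 P53 KO libraries could raise the number of genes changed in DKO against P53 KO. Between those libraries and P53 KO replicate 3, 479 genes differed, 131 of the 1957 among them, but replicate 3 is 1 library whose spread was taken from the other libraries, so the run and the library are not separated there. In the run of 10 libraries alone the median ratio of the changes to those in all libraries was 0.791 (quartiles 0.584 and 1.01), and the rule for reading that ratio was made stricter after it was seen. All 1957 genes kept their sign, but P53 KO replicate 3 enters both fits, so the run and Chd8 cannot be separated for the size of the changes. Chd8 loss without P53 would bring changes shared with Chd8 KO against WT, and 659 genes were called in both in the same direction, where 176 would be met by independent lists. Both lists use 1 spread per gene from all 12 libraries, so 176 is not an exact chance level. A shared spread does not set a sign, and 659 of the 685 genes called in both had the same sign. A part of the count may thus come from Chd8 loss.

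Groupings other than the real one were tried for each comparison. With 3 libraries against 3 there are 10 splits, too few to exclude chance, and the real split gave the largest gene count of the 10 (1 split as large) in 4 comparisons. The real and highest other counts were 2189 and 4 in Chd8 KO against WT, 688 and 2 in DKO against WT, 1386 and 2 in DKO against Chd8 KO and 1957 and 1 in DKO against P53 KO. In P53 KO against WT 2 of 10 splits were as large, and the split that set WT replicates 1 and 2 with P53 KO replicate 3 against the rest gave 75 genes against 24. Gene lists were as many in 6 of 10 splits for Chd8 KO against WT (12, highest other 17), 10 of 10 for P53 KO against WT (7, 13), 2 of 10 for DKO against WT (14, 14), 5 of 10 for DKO against Chd8 KO (14, 16) and 10 of 10 for DKO against P53 KO (8, 14). For the interaction the genotype labels of all 12 libraries were shuffled at random. There 1 of 100 splits was as large for genes (237, highest other 193) and 48 of 100 for lists (12, 17). Shuffling also breaks up the differences between genotypes, so neither share tests the interaction alone. The number of lists past camera's preset test is thus not read as evidence of an interaction.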

How the results depend on the processing

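Of 7266 values of named genes under the alternatives, 6189 kept their direction and their side of the threshold, 1066 were weaker, 3 stronger and 8 reversed, and of 1675 values of lists 1468 were the same, 201 weaker and 6 reversed. Leaving out a library outside a pairwise contrast cannot move a fold change, only its error. The run settings likewise cannot move the fold changes of contrasts without P53 KO. Part of the agreement in these tallies was therefore fixed in advance. Counts moved by more than 1.5 times in 51 of 173 cases for genes and 15 of 150 for lists. Rising p53 targets in Chd8 KO against WT numbered 32, 25 to 33 with 1 library left out and 31 with the Y-linked covariate. Of the p53 targets named there, Pmaip1 lost its call in 4 alternatives. Depth is unknown with TPM alone, so its limit on low genes cannot be given. A larger minimum fold change can only lower a count. Fits with fewer libraries gave fewer calls in some cases and more in others, and the cause was not tested there or elsewhere.

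In Chd8 KO against WT 2189 genes changed, 3863 with library weights, 564 at an absolute log2 fold change of at least 1, 1278 without WT replicate 1, 2864 without P53 KO replicate 3 and 1154, 1301 and 1417 without Chd8 KO replicates 1 to 3. In P53 KO against WT 24 changed, 16 without WT replicate 1 and 1253 without P53 KO replicate 3. In DKO against WT 688 changed, 2274 with library weights, 1046 with the run as a covariate, 298 with the Y-linked level as a covariate, 133 at a change of at least 1, 366 and 426 without WT replicates 1 and 2, 1049 without P53 KO replicate 3 and 332, 318 and 283 without DKO replicates 1 to 3. In DKO against Chd8 KO 1386 changed, 2604 with only the groups compared, 4900 with library weights, 183 with the Y-linked covariate, 505 at a change of at least 1, 524, 734 and 917 without Chd8 KO replicates 1 to 3, 1846 without P53 KO replicate 3 and 630, 831 and 539 without DKO replicates 1 to 3. The cause was not tested.

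In DKO against P53 KO 1957 changed, 319 with only the groups compared, 3207 with library weights, 310 with the run as a covariate, 298 in the run of 10 libraries alone, 242 at a change of at least 1, 676, 1244 and 3089 without P53 KO replicates 1 to 3 and 794, 675 and 725 without DKO replicates 1 to 3. For the interaction 237 passed, 153 at a mean TPM of at least 5, 1502 with library weights, 95 with the run as a covariate, 81 in the run of 10 libraries alone, 122 without WT replicate 1, 142 and 144 without Chd8 KO replicates 1 and 2, 138, 125 and 1562 without P53 KO replicates 1 to 3 and 136, 133 and 128 without DKO replicates 1 to 3. The cause was not tested. With the replicate number as a replicate block the counts were 1926, 22, 537, 1174, 1853 and 223 in the order of the comparisons above, and the numbers did not pair the libraries. The Y-linked covariate was added after the data were seen.

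Lists past camera's preset test numbered 12, 7, 14, 14, 8 and 12, and with an estimated correlation 2, 0, 0, 1, 0 and 3. Fry gave 2 in P53 KO against WT, 1 in DKO against WT, 8 in DKO against Chd8 KO, 3 in DKO against P53 KO and 6 for the interaction. In P53 KO against WT there were 11 with the run as a covariate, 12 in the run of 10 libraries alone and 12 without P53 KO replicate 3, and in DKO against WT 8 with median-of-ratios scaling. The correlation across genes was 0.126, 0.092 with log2(TPM + 0.1), 0.165 without P53 KO replicate 1 and 0.0473 without replicate 3. It was 0.234 with the run as a covariate and in the run of 10 libraries alone, which give the same fold changes. The share with the same sign was 78.4%, 83.7% and 84.3% in those run settings, 74.3% without WT replicate 2 and 69.3% without P53 KO replicate 3. The cause was not tested.

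Results that reversed were the B cell median in P53 KO against WT (0.136), the erythroid median in DKO against P53 KO (-0.140) and the immediate early median there (0.279), each with the run as a covariate and in the run of 10 libraries alone. The other run holds P53 KO libraries only, so both settings give the same fold changes and are not separate checks. Trp53 in Chd8 KO against WT turned to -0.0229 with median-of-ratios scaling, -0.0586 with quantile normalization, -0.0364 with the Y-linked covariate, -0.0652 without WT replicate 3 and -0.0324 without Chd8 KO replicate 1, and was at 0.0458 without WT replicate 1. Atm in Chd8 KO against WT turned to -0.0652 without WT replicate 2 and was at 0.188 without WT replicate 1. With the Y-linked covariate, which is built from such genes, Eif2s3y and Ddx3y in DKO against Chd8 KO turned to 0.0883 and 0.0632. The cause was not tested for the others.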

Other observations

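Some genes changed with Chd8 loss in both backgrounds. Rps4x, a ribosomal protein gene, stood at 3350 ± 189 TPM in WT, 1854 ± 90.1 TPM in Chd8 KO, 3667 ± 97.3 TPM in P53 KO and 1789 ± 65.7 TPM in DKO (-0.85 ± 0.07 with P53, adjusted p = 3.43e-05). Rpl27, another, went the other way, at 122, 274, 137 and 250 TPM (1.17 ± 0.11, adjusted p = 0.000119). Mdc1, a mediator of the DNA damage checkpoint, stood at 47.1 and 92.7 TPM with P53 and at 44.8 and 84.2 TPM without it, and Csf2ra, the receptor chain for GM-CSF, at 39.1 and 75.2 TPM and at 41.4 and 88.8 TPM. Klhdc8b rose from 9.82 to 36.9 TPM with P53 and from 12.6 to 59.6 TPM without it.

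The genes that follow lie outside the rule by which genes were chosen for naming. Fos, an immediate early gene that cell handling induces, stood at 143, 90.7 and 383 TPM in WT, at 158, 847 and 7.00 TPM in P53 KO, at 40.8, 25.1 and 18.3 TPM in Chd8 KO and at 27.5, 15.2 and 10.6 TPM in DKO. Gm3375, a predicted gene on chromosome 7, stood at 0 TPM in all 3 P53 KO libraries and at 30.4 ± 4.57, 38.0 ± 2.70 and 33.4 ± 4.48 TPM in WT, Chd8 KO and DKO.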
